A study of Homo sapiens with 6 samples.

How the data were processed

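RNA was profiled on 6 Affymetrix expression arrays from SKW cells, a human B lymphoblastoid line. The cells had been transduced with a lentiviral vector for ABF-1-GFP or for GFP alone. The sample titles do not say whether ABF-1 and GFP were fused. ABF-1, activated B-cell factor 1, is the basic helix-loop-helix protein encoded by MSC (musculin). Each group held 3 arrays, 1 from each of 3 numbered batches, all at day 8. Groups and batch numbers were taken from the sample titles. Nothing in the labels says whether the batches were separate transductions or separate cultures, so p-values measure the spread between these arrays, which may be partly technical.

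The authors deposited 1 table of probe set intensities on a linear scale, with 54675 probe sets and 6 arrays. Per the submitters' processing notes, the values were made with RMA, which corrects background, quantile-normalizes probe intensities and summarises them per probe set. The version, and whether all arrays were processed together, are not given in the sources used here. RMA values are usually in log2. The deposited intensity values run from 4.13 to 42348, so log2 was taken before every test. The median intensity of the 2 arrays of a batch was close, and it differed between batches. It was 76.8 and 74.4 in batch 1, 52.1 and 50.7 in batch 2, and 34.9 and 34.4 in batch 3, for GFP and ABF-1-GFP respectively. Quantile normalization gives arrays that are run together the same distribution of probe intensities. These medians therefore argue against a single run over all 6 arrays with no later scaling. The deposited intensity table gives no detection calls, so dim probe sets could not be told from background, and the number of arrays limits the precision. Folds at low intensity can be understated by the background that remains in the signal.

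Probe sets were named from the platform annotation. Of all probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none there. Of those with 1 symbol, 41043 had an Entrez ID that matched the RefSeq gene table. The 62 control probe sets were left out, as were probe sets with several symbols or none. For each gene the probe set with the highest mean over all 6 arrays was used, which left 19775 genes. No intensity filter was applied.

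The comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Before the data were examined, the main fit was set without a batch term, and the fit with the batch as a block was set as its alternative. The batch numbers pair the arrays, since the titles give each number to 1 array of each group as a shared batch. Deviations of the arrays from their group means correlated between the 2 arrays of a batch at r = 0.71, 0.72 and 0.79 in batches 1, 2 and 3, across genes. Both fits give the same log2 changes and differ in their standard errors. Errors given below as SE come from the fit with the block, with n = 3 pairs, unless stated.

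Also fixed before the data were examined were 31 gene lists for the cell type and the question. They held 735 entries and 683 distinct genes, of which 668 entries and 622 genes were measured. The other members are not reported here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. With the block, the estimated setting gave a larger p even for lists whose estimate lay under 0.01. For plasma cell genes (estimate -0.032) the unadjusted camera p went from 0.10 to 0.21. For B cell transcription factors (-0.050) it went from 0.16 to 0.26. That setting also takes its p from the few residual degrees of freedom of these arrays, which the preset setting does not. Without the block, its estimate holds the differences between batches as well. A call lost under that setting therefore cannot be put down to correlation between members alone, and it says little about any single list. The lists covered plasma cells, the unfolded protein response, immunoglobulins, B cell transcription factors, B cell surface genes, germinal centre and memory B cells, E proteins, E2A targets, NF-kB targets and the interferon response. They also covered MHC class I and II, the cell cycle (3 lists), cell death, p53 targets, MYC targets, glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, cytokines, chemokines and adhesion, Hodgkin lymphoma, immediate early genes and myogenic genes. A further 3 lists held markers of other cells: T and NK cells, myeloid cells, and fibroblasts or epithelial cells. Within each batch, a list's median change was ranked among the medians of 10000 random lists matched on mean intensity in 20 bins.

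Genes were named by a rule set before the data were examined. It took the 12 largest rises and falls among genes past the threshold with the same sign in all 3 batches. Where fewer than 10 passed in a direction, it filled up to 10 by the smallest p and these are stated as not passing. It also took a fixed set of regulators and markers, 14 of them measured, and up to 4 members of each list with the smallest p without the block. The same rule was applied to the blocked fit, and every gene past the threshold there is named.

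Both fits were tested on simulated arrays with the real means and batch differences, 19775 genes and known changes in 200 genes, 50 of each size. For ABF-1-GFP against GFP, the fit without the block found 0 of 50 genes at each of the log2 changes 0.5, 1, 1.5 and 2. The fit with the block found 4, 42, 50 and 50 of 50, all with the right sign, and 7 unchanged genes. The simulated spread was the same in every batch. The real pairwise differences had an SD over genes of 0.35, 0.25 and 0.19 in batches 1, 2 and 3. These counts therefore hold only for batches of even spread. In the same simulation camera found a list shifted by 0.4, with or without the block, and none of the other 30 lists. The simulated noise was drawn independently for each gene. It therefore does not measure how often camera calls lists in error where members move together. On the real arrays with the block, splits other than the true one gave 5 to 8 lists. Each of these splits reverses 1 batch and keeps part of any real difference, so they do not measure it either.

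The alternatives were the batch block, an intensity trend in the spread, genes under the median mean intensity left out, the mean of a gene's probe sets, every probe set with 1 gene symbol tested separately, median centring, quantile normalization over all 6 arrays, a 2-fold minimum, an estimated inter-gene correlation, and leaving out each array or batch. The same alternatives run with the block were added after seeing the data. No genome was used, and no coordinates are given.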

Results

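The data were 6 Affymetrix expression arrays of SKW B lymphoblastoid cells at day 8, 3 from cells carrying an ABF-1-GFP vector and 3 from cells carrying GFP alone. Each of 3 batches held 1 array of each group. Arrays of the same batch correlated at r = 0.987 to 0.996 over all probe sets on the log2 scale, and arrays of different batches at 0.964 to 0.983, whatever their group. The series asked what enforced ABF-1 expression changes in the transcriptome of these cells.

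The MSC transcript, which encodes ABF-1, was examined first. Its only probe set read 954, 824 and 509 in the GFP arrays of batches 1, 2 and 3. It read 1555, 613 and 464 in the arrays labelled ABF-1-GFP. The log2 change was 0.05 ± 0.20 (SE, n = 3 pairs; limma adjusted p = 0.95 with the batch as a block and 1 without). It was 0.70 in batch 1, -0.43 in batch 2 and -0.13 in batch 3, so this probe set did not show the enforced expression. Whether it covers the part of MSC carried by the vector is not given in the sources used here. A probe set outside that part would not check the labels, so every direction below rests on the labels alone.

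With the batch as a block, 20 genes rose and 5 fell in the arrays labelled ABF-1-GFP, all 25 in the same direction in all 3 batches. The genes that rose included the Fc receptor-like B cell receptors FCRL2, FCRL4 and FCRL5, the RNA-sensing receptor TLR7, interferon-induced genes (IFIT1, IFI44, IFI44L, DDX60, EPSTI1), and the chemokines CCL2 and CCL4. JCHAIN, which encodes the chain that joins polymeric IgM and IgA, fell by 2.03 ± 0.21 on the log2 scale, to 0.245 of its level. FCRL5 rose 3.15-fold, FCRL2 3.46-fold, FCRL4 2.95-fold and TLR7 2.13-fold. Of the 25 genes, 16 rose and 1 fell by at least 2-fold. Without the block no gene passed the threshold, because the standard error then holds the differences between batches. Its median was 0.46 without the block and 0.11 with it. The lowest limma adjusted p without the block was 0.065, and 61 genes had an unadjusted p under 0.05, where 989 would by chance. With the block 1565 genes did.

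The rise of FCRL2, FCRL4 and FCRL5 was seen in each batch. The log2 change of FCRL5 was 1.66, 1.84 and 1.45 in batches 1, 2 and 3 (limma adjusted p = 0.019 with the block). FCRL4, a receptor of a tissue memory B cell subset, changed by 1.17, 1.40 and 2.12 (adjusted p = 0.037). FCRL2 changed by 2.38, 1.28 and 1.72 (adjusted p = 0.033), although 1 of its 5 probe sets differed by -0.064 and another by 0.13. JCHAIN read 389, 197 and 508 with GFP and 113, 29.7 and 170 with ABF-1-GFP (adjusted p = 0.032).

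**Figure D1:**
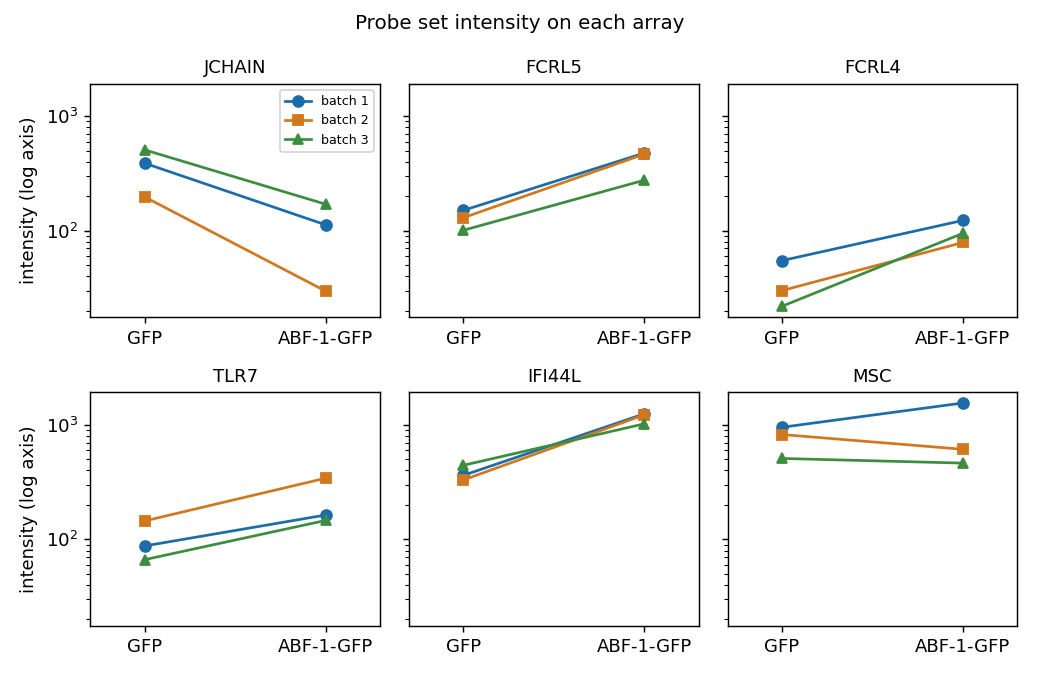
Intensity of 1 probe set per gene on each array (vertical log axis, the deposited linear values), with GFP on the left and ABF-1-GFP on the right and a line joining the 2 arrays of a batch. JCHAIN was lower and FCRL5, FCRL4, TLR7 and IFI44L were higher with ABF-1-GFP in all 3 batches, while MSC was higher in batch 1 and lower in batches 2 and 3.

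Other genes that rose with the block lie outside the FCRL family and the interferon response. PAG1, a membrane adaptor of Src-family kinase signalling, rose 3.97-fold, and ZAP70, a kinase of T cell receptor signalling, rose 3.64-fold (log2 change 1.86 ± 0.17, limma adjusted p = 0.020). CCL2 rose 3.60-fold and CCL4 2.02-fold. The rise of CCL4 was 0.99, 1.08 and 0.97 in the 3 batches on the log2 scale. SLC51B, a subunit of a bile acid and steroid transporter, rose 2.79-fold, the adhesion molecule CHL1 2.48-fold and the tetraspanin TSPAN33 2.02-fold. SH3TC1, MAB21L3, ABTB2 and PDP1, a pyruvate dehydrogenase phosphatase, rose by 0.83 to 1.00 on the log2 scale. Besides JCHAIN, the genes that fell were the inflammasome sensor NLRP3 (-0.98 ± 0.11), the galectin gene LGALS2 (-0.98 ± 0.11), the glycerolipid enzyme GPAT3 (-0.95 ± 0.11) and the apoptotic nuclease gene DFFB (-0.89 ± 0.10). Of the 13 called genes with more than 1 probe set, 11 had all their probe sets on 1 side of 0. The exceptions were FCRL2 and SH3TC1. A shared sign did not mean a change of like size. The dimmest probe sets of FCRL5, ABTB2 and NLRP3 differed by 0.093, 0.11 and -0.17, while those of IFI44 and PDP1 differed by 0.96 and 0.66.

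**Figure D2:**
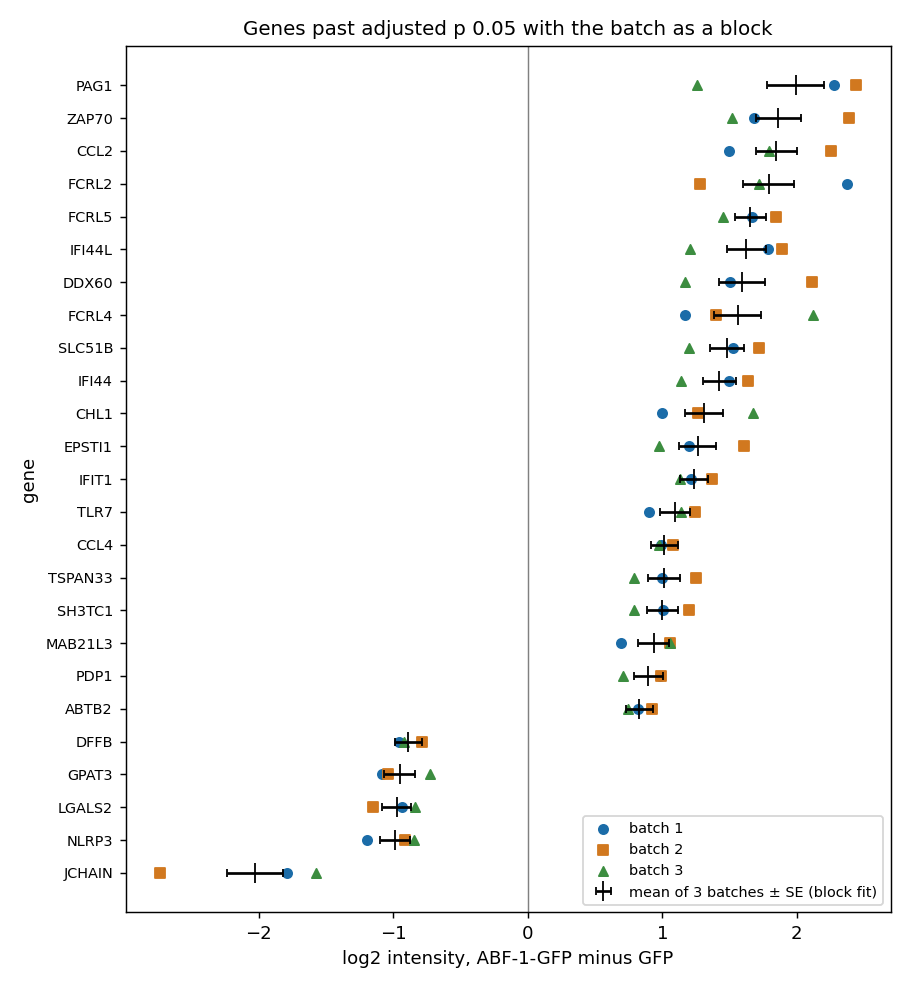
Log2 intensity difference, ABF-1-GFP minus GFP (horizontal axis), for the 25 genes past a limma adjusted p of 0.05 with the batch as a block, 1 gene per line; coloured symbols are the 3 batches and black bars the mean ± SE of the blocked fit. All 3 batches lie on the same side of 0 for every gene shown.

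Without the block, the genes named by the rule did not pass the threshold. Those with the smallest p among genes higher in all batches were ZNF423, PAG1, IFI27, ZAP70, FCRL2, FCRL5, IFI44L, CCL2, DDX60 and FCRL4. ZNF423, a zinc-finger factor that binds the B cell factor EBF1, differed by 0.89, 5.27 and 2.12 in the 3 batches (limma adjusted p = 0.065 without the block and 0.36 with it). Among genes lower in all batches they were JCHAIN, FLI1, SPP1, HAVCR2, HMGCS1, NLRP3, LGALS2, SMIM14, HHLA2 and CHST4. The ETS factor FLI1 differed by -1.48 ± 0.19 and SPP1, which encodes osteopontin, by -1.21 ± 0.16. Both had an adjusted p of 0.051 with the block, as did CHST4. With the block, the rule filled the genes that fell with CHST4, FGF14, FLI1, SPP1 and NDST4, which did not pass.

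The number of genes called depended on the batches. With the block, leaving out batch 1 gave 138 genes (97 higher, 41 lower) and leaving out batch 2 gave 101 (76 higher, 25 lower), and each set held all 25. Leaving out batch 3 gave 4 genes, 3 of them among the 25, and leaving out the genes under the median mean intensity gave 0 (lowest limma adjusted p = 0.071). The pairwise differences were widest in batch 1, with an SD over genes of 0.35 against 0.25 in batch 2 and 0.19 in batch 3. Their correlation across genes, which are not independent replicates, was 0.17 between batches 1 and 2, 0.17 between 1 and 3, and 0.35 between 2 and 3.

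The interferon response list stood apart. Of its 33 measured genes, 25 were higher in all 3 batches and 2 were lower in all 3, where 30.7% of all genes kept 1 sign, in either direction. Of all 19775 genes, 2368 were higher and 3711 lower in all 3 batches. Adjusted over all genes tested, 4 rose with the block (IFIT1, IFI44, IFI44L and DDX60) and none without it. Adjusted over the list alone, 22 rose with the block, 11 did not pass and none fell, and 4 rose without it. IFI44L changed by 1.63 ± 0.15, DDX60 by 1.59 ± 0.17, IFI44 by 1.42 ± 0.12 and IFI27 by 1.92 ± 0.27 (limma adjusted p = 0.059 for IFI27 over all genes with the block). The median change of the list was 0.44, 0.68 and 0.36 in batches 1, 2 and 3, above all 10000 random lists in each batch. Camera gave an adjusted p of 1.1e-58 without the block and 2.3e-26 with it, and 2.5e-31 to 4.2e-21 over the blocked alternatives at the preset correlation. With an estimated correlation the adjusted p was 0.37 without the block and 0.61 with it, and the unadjusted p 0.012 and 0.037. The estimate was 0.55 without the block, where it also holds the differences between batches, and 0.16 with it.

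**Figure D3:**
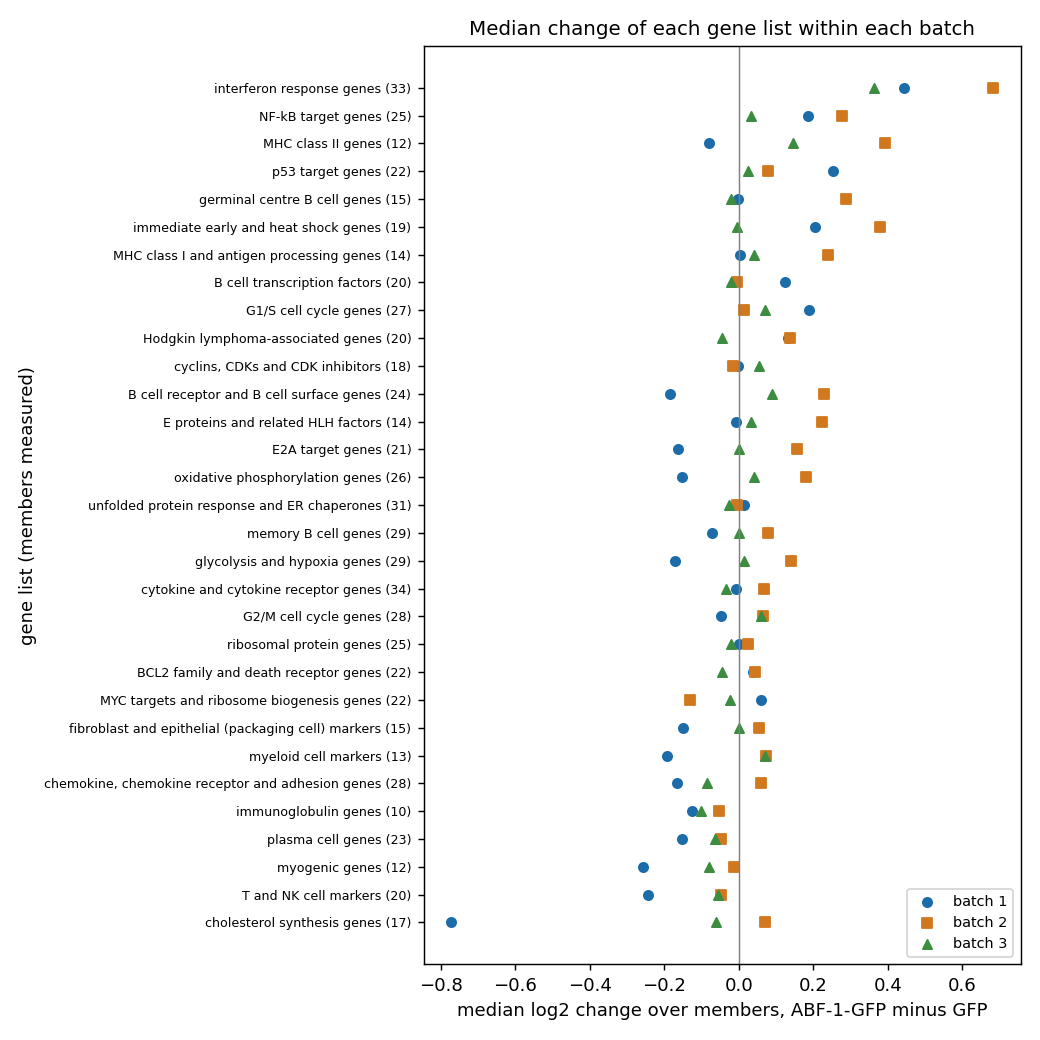
Median log2 change over the measured members of each of the 31 gene lists (horizontal axis, ABF-1-GFP minus GFP) within each batch, with the number of measured members in brackets. The interferon response list has the highest median in all 3 batches, and the low median of the cholesterol synthesis list (-0.77) is that of batch 1.

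Genes of plasma cells and of memory B cells were the lists closest to the question. Of 23 plasma cell genes, JCHAIN fell with the block and 22 did not pass, with the same count adjusted over the list alone. PRDM1, which encodes the plasma cell regulator Blimp-1, differed by -0.07 ± 0.10, XBP1 by 0.43 ± 0.19, IRF4 by -0.20 ± 0.16 and the plasma cell surface gene SDC1 by -0.19 ± 0.10. CAV1 differed by 0.58 ± 0.22 (-0.15, 0.87 and 1.03 in batches 1, 2 and 3) and the kinase gene PIM2 by -0.38 ± 0.17. The median change over the list was -0.07, with 3 members higher and 5 lower in all 3 batches. In batches 1, 2 and 3 the median was -0.15, -0.047 and -0.063, above 9.3%, 4.8% and 2.3% of the random lists. The list was lower by camera without the block (adjusted p = 0.039), not with it (0.21), and not with an estimated correlation (adjusted p = 0.97 without the block). Without the block it also did not pass after centring (0.27) or quantile normalization (0.18), without any 1 batch (0.094 to 0.25), or without any 1 array (0.069 to 0.28) except the GFP array of batch 1 or the ABF-1-GFP array of batch 3. Of 10 immunoglobulin genes, none passed (camera adjusted p = 0.31 without the block and 0.24 with it). IGHM, the heavy chain of IgM, differed by -0.38 ± 0.12 and IGHG1 by -0.25 ± 0.10.

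Of 29 memory B cell genes, FCRL4, FCRL5 and TLR7 rose with the block and 26 did not pass. Adjusted over the list alone, the same 3 rose, and HHEX, a homeobox factor of memory B cells, fell by 0.52 ± 0.11. CD27, the classical memory marker, differed by 0.07 ± 0.12. Over the list, the median change was 0.012, and it was -0.07, 0.08 and 0 in batches 1, 2 and 3. In all 3 batches 8 members were higher and 7 were lower, so the members did not share a direction. The list was higher by camera without the block (adjusted p = 0.0026), not with it (0.21), and not with an estimated correlation (adjusted p = 0.97). Without the block it also did not pass without the genes under the median mean intensity (0.49), after centring (0.23) or quantile normalization (0.38), without batch 2 (0.10), or without the ABF-1-GFP array of batch 2 (0.11) or batch 3 (0.091). With the block its direction turned without the genes under the median mean intensity (0.94). Without the block FCRL4 and FCRL5 passed adjusted over the list alone. The B cell factors PAX5, BCL6 and BACH2 differed by 0.20 ± 0.11, -0.16 ± 0.10 and -0.15 ± 0.11 and did not pass. The B cell transcription factor list did not pass as a whole (camera adjusted p = 0.24 with the block). Adjusted over the list alone with the block, HHEX was its only member to pass. Of 24 B cell surface genes, CD72, an inhibitory co-receptor, rose by 0.91 ± 0.16, adjusted over the list alone with the block. That list did not pass (camera adjusted p = 0.054 without the block and 0.078 with it). Its median change was -0.18, 0.23 and 0.09 in batches 1, 2 and 3, and it was higher without batch 1 (2.7e-05 and 0.00086), without the ABF-1-GFP array of batch 1 (0.0061 without the block) and with the mean of a gene's probe sets (0.014 and 0.028). An intensity trend in the spread gave 0.035 without the block. The range over the blocked alternatives was 0.00086 to 0.70.

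ABF-1 belongs to the helix-loop-helix proteins, so its relatives were read as a list of 14 genes. None passed over all genes. Adjusted over the list alone with the block, 3 rose and 1 fell. Those that rose were HES1 (0.64 ± 0.12) and HEY1 (0.47 ± 0.11), both Notch-responsive repressors, and ID2 (0.41 ± 0.12), an inhibitor of E proteins. TCF3, which encodes the E2A proteins, fell by 0.38 ± 0.11. The other probe sets of HES1 differed by 0.48 and -0.065, and those of TCF3 by -0.43 to 0.028. ID3 differed by 0.57 ± 0.20 and TCF4 by -0.09 ± 0.10, and neither passed. Camera placed the list higher (adjusted p = 0.020 without the block and 0.036 with it), not with an estimated correlation (adjusted p = 0.97 and 0.61) and not without batch 2 (0.34, with a range of 0.0082 to 0.34 over the blocked alternatives). It also did not pass without the genes under the median mean intensity (0.069 without the block and 0.11 with it), after centring (0.056 and 0.052) or, without the block, after quantile normalization (0.069). Without the block, leaving out 1 array ended the call for the ABF-1-GFP array of batch 1 (0.20), the GFP and ABF-1-GFP arrays of batch 2 (0.30 and 0.17) and the GFP array of batch 3 (0.22). The 21 E2A target genes did not pass (camera adjusted p = 0.31 and 0.22).

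NF-kB target genes were the other list that camera called in all 8 blocked alternatives at the preset correlation, as it did the interferon list. Of 25 genes, 11 were higher in all 3 batches and 3 lower, against 2368 and 3711 of all 19775 genes. CCL4 rose and 24 did not pass, adjusted over all genes or over the list alone with the block. CD83, a surface protein of activated B cells, differed by 0.40 ± 0.12 and NFKB2 by 0.43 ± 0.13. Camera gave an adjusted p of 3.7e-05 without the block and 3.9e-05 with it, and 6.1e-06 to 0.0069 over those alternatives. It did not pass with an estimated correlation (adjusted p = 0.97 and 0.61).

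A further 6 lists passed camera both without and with the block, and each lost its call when 1 batch was left out. Each also lost it when the correlation was estimated (adjusted p = 0.61 or more with the block), a setting that none of the 31 lists passed. That loss therefore does not set these 6 lists apart. Without the block, each also lost its call when some single array was left out. Ranges below are over the blocked alternatives at the preset correlation. MHC class II genes were higher (adjusted p = 0.0037 and 0.0011, 6 of 12 higher in all batches, HLA-DRB1 0.34 ± 0.11), with 0.34 without batch 2 and a range of 7.3e-07 to 0.34. Germinal centre genes were higher (0.0094 and 0.030; RGS13 0.53 ± 0.20, EZH2 0.44 ± 0.15), with a range of 0.0072 to 0.30. Their median change was -0.0012, 0.29 and -0.020 in batches 1, 2 and 3. In the same order, RGS13 differed by 1.17, 0.31 and 0.10 and EZH2 by 0.89, 0.29 and 0.14. RGS13 was dim (mean log2 intensity 3.38), and its other probe sets differed by 0.078 and -0.14. The germinal centre list did not pass without batch 2 (0.30), without the genes under the median mean intensity (0.32 without the block and 0.29 with it) or with the mean of a gene's probe sets (0.19 and 0.21). Immediate early genes were higher (0.0012 and 0.011), with a range of 0.0019 to 0.34. They did not pass without batch 2 (0.34) or without the genes under the median mean intensity (0.14), both with the block, or without the block after centring (0.052) or quantile normalization (0.077). Among them JUN rose by 0.50 ± 0.10, adjusted over the list alone with the block, and EGR1 differed by 0.78 ± 0.24. The other probe sets of JUN differed by 0.09, 0.075 and 0.31. The p53 targets were higher (0.00050 and 0.00044; GADD45A 0.69 ± 0.16), with 0.051 without batch 1 and a range of 5.0e-05 to 0.051. Genes of the G1/S phase were higher (0.011 and 0.0069), with a range of 0.00039 to 0.56. They did not pass without batch 1 (0.56 with the block) or without the genes under the median mean intensity (0.21 without the block and 0.14 with it), and their direction turned without the GFP array of batch 1 (0.092 without the block). Among them the cell cycle factor E2F2 rose by 0.74 ± 0.14, adjusted over the list alone with the block. Cholesterol synthesis genes were lower (3.0e-07 and 0.011), with a range of 5.4e-09 to 0.74. Without batch 1 their direction turned (0.74). HMGCS1 differed by -2.40, -0.64 and -0.10 and SQLE by -1.76, -0.24 and -0.11 in batches 1, 2 and 3. None of the members of these 6 lists passed over all genes.

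Of the marker lists for other cells, T and NK cell markers had a median change of -0.13, with ZAP70 the only 1 of 20 to rise. Myeloid markers had a median of -0.03 and none of 13 passed. Of 15 fibroblast and epithelial markers, CDH1 (0.76 ± 0.14) and THY1 (0.43 ± 0.11) rose, adjusted over the list alone with the block, although the other probe set of CDH1 differed by 0.05. The list's median was -0.03. None of these 3 lists passed camera (adjusted p = 0.72, 0.72 and 0.41 without the block and 0.11, 0.60 and 0.48 with it).

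The remaining lists did not pass either with all arrays. Camera adjusted p without and with the block was 0.26 and 0.22 for the unfolded protein response, 0.23 and 0.071 for MHC class I, 0.41 and 0.22 for G2/M genes, and 0.42 and 0.31 for cyclins and their inhibitors. It was 0.60 and 0.37 for cell death genes, 0.80 and 0.74 for MYC targets, 0.80 and 0.51 for glycolysis, 0.72 and 0.38 for oxidative phosphorylation, and 0.86 and 0.68 for ribosomal proteins. It was 0.47 and 0.33 for cytokines, 0.90 and 0.74 for chemokines and adhesion genes, 0.10 and 0.11 for Hodgkin lymphoma-associated genes, and 0.58 and 0.46 for myogenic genes. Leaving out arrays brought some of these lists past the threshold. Without batch 1, MHC class I (0.024 without the block and 0.0093 with it), oxidative phosphorylation (0.00998 and 0.0021) and glycolysis (0.020 and 0.023) were higher, and MYC targets were lower with the block (0.036). The glycolysis list had no stable direction without the block. It was higher without the GFP array of batch 1 (7.0e-07) or the ABF-1-GFP array of batch 2 (0.00025), and lower without the ABF-1-GFP array of batch 1 (0.0093) or the GFP array of batch 2 (1.8e-07). Also without the block, MHC class I was higher without the ABF-1-GFP array of batch 1 (0.0095) or the GFP array of batch 3 (0.031), oxidative phosphorylation was higher without the ABF-1-GFP array of batch 1 (0.00065), and MYC targets were lower without the GFP array of batch 1 (0.011). Hodgkin lymphoma-associated genes were higher without batch 3 (0.042 and 0.031) and, without the block, with an intensity trend in the spread (0.046). That trend brought MHC class I to 0.026 with the block. The cell death and the fibroblast and epithelial lists had a median below 0 and a camera direction above 0. The glycolysis and ribosomal protein lists had a mean below 0, with their median and camera direction above 0.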

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

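The alternatives run with the batch as a block were chosen after the data were seen, and the cause of each change was not tested unless stated. Without the block the gene count of 0 became 25 with the replicate block, 1 with an intensity trend in the spread, 2 with the mean of a gene's probe sets and 2 with every probe set that has 1 gene symbol tested separately. It ranged from 0 to 7 when 1 array or 1 batch was left out, with 5 without the GFP array of batch 1, 7 without the ABF-1-GFP array of batch 1, 1 without the GFP array of batch 3 and 3 without the ABF-1-GFP array of batch 3. With the block, the 25 genes became 0 without the block, 0 with genes under the median mean intensity left out, 16 with the mean of a gene's probe sets (15 of them among the 25), 16 with every probe set that has 1 gene symbol tested separately (10 of them shared), and 38 with each array centred on its median (all 25 among them). Over all 54613 probe sets but the controls, named or not, 8 probe sets were called with the block. The 25 genes ranged from 4 to 138 when 1 batch was left out. Quantile normalization over all 6 arrays gave 23, of which 22 were shared, an intensity trend 21 and a 2-fold minimum 17. In 219 combinations of 1 of the 25 genes and an alternative, the gene was past the threshold in 136. The 11 lists called without the block became 7 with genes under the median mean intensity left out, 7 after centring, 7 after quantile normalization and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. They ranged from 5 to 11 when an array or batch was left out, the lowest without batch 2 or its ABF-1-GFP array. The 9 lists called with the block became 5 with genes under the median mean intensity left out and 0 with an estimated correlation, and ranged from 5 to 11 without 1 batch. The block ended the calls of the plasma cell and memory B cell lists and of no other list. The median change over all genes was -0.10 in batch 1, against -0.0014 in batch 2 and 0 in batch 3. The log2 changes given for batch 1 include that shift, which was not subtracted. Leaving out 1 array or batch without the block turned the sign of some genes that never passed. The range was -0.47 to 0.40 for MSC, -0.30 to 0.11 for PRDM1, -0.16 to 0.95 for XBP1, -0.57 to 0.00010 for IRF4, -0.62 to 0.31 for BCL6, -0.66 to 0.31 for BACH2, -0.47 to 0.23 for TCF4, -0.20 to 0.40 for CD27, -0.67 to 0.080 for PIM2, -0.19 to 1.13 for NFKB2, -0.16 to 1.41 for EGR1 and -0.84 to 0.32 for IGHG1. MSC has 1 probe set, so testing its probe sets separately changed nothing. Signal over background could not be judged, since the table gives no detection calls.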

Other observations

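The tests of explanations in this part, the counts over other splits of the arrays included, were run after the results were seen. Within the FCRL family, chosen after its values were seen, some members passed and others did not, and the difference between members was not tested. FCRL2, FCRL4 and FCRL5 rose by 1.56 to 1.79 on the log2 scale, while FCRL1 differed by 0.11 ± 0.11, FCRL3 by 0.25 ± 0.16, FCRLA by 0.29 ± 0.10 and FCRLB by -0.13 ± 0.10, none past the threshold. Centring each array or quantile normalization turned none of the 7 directions and moved none of the 7 genes across the threshold. FCRLA was among the brighter genes (mean log2 intensity 10.5). FCRL1 (3.93) and FCRL3 (4.09) were among the dim ones, where a change would be hard to see. FCRL3 differed by -0.03, 0.05 and 0.74 in batches 1, 2 and 3. GATA3, a T cell factor on the Hodgkin lymphoma list, differed by 0.49, 0.49 and 0.50 in the 3 batches (0.49 ± 0.10, limma adjusted p = 0.20 with the block over all genes), and it rose adjusted over its list alone. JUN, on the same list, was the other member to rise there, on 1 of its probe sets.

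The MSC probe set was not higher in the arrays labelled ABF-1-GFP. A swap of the 2 labels within 1 batch is argued against: of the genes that moved 1 way by at least 0.5 in both other batches, 86.5% (135 of 156) moved that way in batch 1, 91.2% (103 of 113) in batch 2 and 92.9% (169 of 182) in batch 3. A probe set outside the transgene stays open, since no probe sequence or vector map was used, and the change of 0.047 would then be that of the endogenous transcript. A swap in all 3 batches together was not tested.

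Of the 33 interferon response genes, 25 were higher in all 3 batches, 2 were lower in all 3 and 6 were mixed, and the list did not pass camera with an estimated correlation (adjusted p = 0.37 without the block and 0.61 with it). Different brightness distributions of the 2 arrays of a batch are argued against as the whole cause, because the list's median change was 0.45 after quantile normalization over all 6 arrays, and 0.35, 0.64 and 0.36 within batches, against 0.49 as deposited. An effect of ABF-1 itself and a difference in vector dose or transduction between the 2 cultures of a batch both remain open and untested, since the arrays carry no measure of the vector. ZAP70 rose in the same arrays. T or NK cells in the cultures are argued against, since the other 19 T and NK cell markers had a median change of -0.14 (upper quartile -0.05), against 1.86 for ZAP70, and none was higher in all batches. The brightest of them, NKG7 and CD5, had a mean log2 intensity of 7.31 and 6.93 and differed by -0.41 ± 0.13 and -0.16 ± 0.12.

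No gene was called without the batch block and 25 were called with it. Quantile normalization over all 6 arrays still gave 0 genes without the block in limma, and the deviations of the 2 arrays of a batch then correlated across genes at 0.68 or more. Without the block the real count is 0, which any split reaches, so that 10 of 10 splits did so tests nothing. The highest other counts, 6020 and 4993 genes, came from the splits with both arrays of batch 1 on 1 side and both of batch 3 on the other, a structure of the arrays by batch. For lists without the block, 2 of 10 splits gave as many as the real 11, the highest other also 11. With the block, 4 splits part every batch. The real 1 alone gave 25 genes and the others 0. Each of the others reverses 1 batch, which puts part of any real difference into the spread. Their counts are therefore not those of arrays without a difference. For lists 1 of 4 splits, the real 1, gave 9, and the highest other gave 8. Splits this few cannot give a share under 0.05.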
